A study of Mus musculus with 5 samples.

How the data were processed

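RNA was sequenced from mouse (CD1) embryonic cortical cells purified by fluorescence for GFP, per the labels' protocols. Cortices had been electroporated at embryonic day 12.5 with a construct carrying Ptf1a and GFP or with a GFP-only construct, and were harvested at embryonic day 15.5. Ptf1a misexpression was represented by 3 samples and the GFP-only control by 2 samples, each pooled from 3 to 6 brains. Between 2.1 and 7.8 ng of total RNA with an integrity number above 8 was amplified with a low-input kit, and libraries made with 10 cycles of amplification were read from both ends at 50 bp on an Illumina HiSeq. Amplification from so little RNA adds variation to weakly expressed genes.

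The authors made the table with CASAVA 1.8.2, TopHat2 2.0.8, Cufflinks 2.1.1 and Cuffdiff on the mouse build mm9, per the submitters' processing notes, with the Cuffdiff version, the gene annotation and all parameters not given in the sources used here. It held 23234 gene rows, and the authors merged the samples of each group into a single FPKM value per gene (fragments scaled to transcript length and to all fragments), per the file headers. The deposited log2 fold change was the Ptf1a value over the control value, and it was infinite where a group stood at 0. The deposited test statistic is a signed score, and the authors' p-value and q-value stood beside it for each tested gene, per the file headers. The group headed PIG in the table was read as the Ptf1a construct, because the other heading was GFP and the samples formed 2 groups. Of the rows, 11876 carried a test, 11194 had no test, 148 were marked as having too little data and 16 as having too much. Among the last, Actb, Stmn1, Tubb3 and Tuba1a were listed at 0 in at least 1 group, so a 0 in this table can be a failed estimate. No per-sample values were analysed here, so no spread between samples, no SD and no depth per sample could be given. The precision of a gene's value is known only through the authors' test: the ratio of deposited log2 fold to test statistic, an implied standard error, had a median of 0.46 for genes between 1 and 5 FPKM and 0.24 for genes over 20 FPKM.

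Genes were called at a deposited q under 0.05, which matched the table's own mark in all 23234 rows. A gene is said to have risen or fallen when it was called, in Ptf1a misexpression relative to the GFP-only control. Log2 differences given without another source were computed here as log2(FPKM + 0.1) in Ptf1a misexpression minus that in the control; the pseudocount of 0.1 understates the change of weak genes. Recomputing the Benjamini-Hochberg adjustment over tested genes gave the deposited q within 5.2e-07. The gene lists (35), the test and the naming rule were fixed before the data were examined. Each list was tested for over- or under-representation among risen and among fallen genes by a two-sided Fisher's exact test against 10484 tested genes with at least 1 FPKM in either group, with Benjamini-Hochberg adjustment over 70 tests. Odds ratios had 0.5 added to each cell of the table. The list's median log2 difference was placed among 10000 random lists matched on mean expression in 20 bins. Fisher's exact test treats genes as independent, and a correlation between genes could not be estimated from single group values. For simulated data, lists of 30 genes were drawn from the same 10484 genes. Planted odds of 4 were recovered in 61.7% of lists and planted odds of 2 in 8.33%, with 0 of 1160 null tests called. A list of that size without a call may therefore still have changed modestly. Smaller lists were not simulated and may miss larger changes: the GABA list, with 6 such members, was uncalled at an odds ratio of 8.25. The null lists were drawn at random, so they do not cover lists whose genes move together. Members absent under their fixed symbol were matched through recorded synonyms, 7 in all.

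The genes named are Ptf1a, the 12 risen and 12 fallen genes with the largest log2 difference at 1 FPKM or more in the higher group, leaving out small RNAs and unnamed models, and up to 4 called members per list with the largest difference. For transmitter, neuropeptide, dorsal horn factor, pyramidal, interneuron and other cell type lists, up to 4 uncalled members with the highest mean FPKM were added. Some genes that the rule names are not reported here. Genes outside this rule are said to have been chosen after their values were seen. Coordinates are those of the authors' table on mm9. Their starts were read as counting from 0 and are printed counting from 1, since 4812 of 17251 loci then had the span of an annotated transcript, against 609 otherwise. Transcript length and GC came from a later annotation (GENCODE M21) and were matched by symbol only.

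Alternatives covered the q threshold, FPKM minimums, fold minimums, pseudocounts, centring, the treatment of unnamed and shared loci and, chosen after seeing the data, calls from the two-sided normal p of the deposited test statistic, tests stratified by expression and lists without Ptf1a or without genes that several lists hold. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.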

Results

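The data describe what happened to cortical cells when Ptf1a, a basic helix-loop-helix factor that specifies inhibitory neurons in the spinal cord, retina and cerebellum and acinar cells in the pancreas, was switched on in them. GFP-positive cells were purified from embryonic mouse cortex 3 days after electroporation, from 3 Ptf1a samples and 2 GFP-only samples. Expression is given as the authors' group values in FPKM, control first and Ptf1a second, with no replicate error beyond the authors' own test.

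Ptf1a misexpression reshaped expression broadly. Of 11876 tested genes, 2217 rose and 2263 fell, and the rises were larger. Ptf1a itself (chromosome 2, 19367290 to 19369128, mm9) went from 0.210 to 38.9 FPKM, a log2 fold of 7.54 with q = 0.000329 in the authors' deposited table; reads from the construct's coding sequence cannot be told from those of the endogenous gene. With small RNAs and unnamed models left out, the largest rises beside it were Ibsp, a bone matrix protein (0.263 to 46.8 FPKM), Kirrel2, an adhesion molecule of the nephrin family (0.403 to 57.1 FPKM), and the pancreatic products Prss2, Ctrb1, Reg1, Reg3b and Cel. Tff2, Clps and Rnase1 were listed at 0 in controls and stood at 4.16, 3.35 and 3.28 FPKM. Prdm13, a zinc finger factor acting with Ptf1a in the dorsal spinal cord, rose from 0.0851 to 7.44 FPKM, and the keratin Krt73 from 0.101 to 7.85 FPKM.

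Small RNAs and unnamed models left out, the largest fall was that of Slc7a11, the cystine and glutamate exchanger (chromosome 3, 50168858 to 50247535, mm9), from 30.0 to 0.189 FPKM, a log2 fold of -7.31 with q = 0.000329 in the authors' deposited table. Defb25 and Cma1 fell from 1.73 and 1.03 FPKM and were listed at 0 with Ptf1a. The thyroid hormone carrier Ttr fell from 31.4 to 6.92 FPKM, the small heat shock gene Hspb3 from 7.17 to 1.30 FPKM, Oca2 from 1.98 to 0.313 FPKM, and Arhgdib from 9.62 to 2.49 FPKM. Hba-x, Dynlrb2, Lhfpl3, Skap1 and Rasgrf1 completed the 12 largest falls. Among risen genes 792 (35.7%) changed at least 2-fold on the log2(FPKM + 0.1) scale and 177 at least 4-fold, against 222 (9.81%) and 14 of the fallen genes. Risen and fallen genes differed in abundance, however. In the lowest of 10 bins of mean expression 394 genes rose and 105 fell, and in the highest 26 rose and 653 fell. Weak genes also had the larger implied standard error. How much of the gap in size follows from abundance was not tested. The 2-fold share of all called genes, 22.6%, was 9.11% with a pseudocount of 1.

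**Figure D1:**
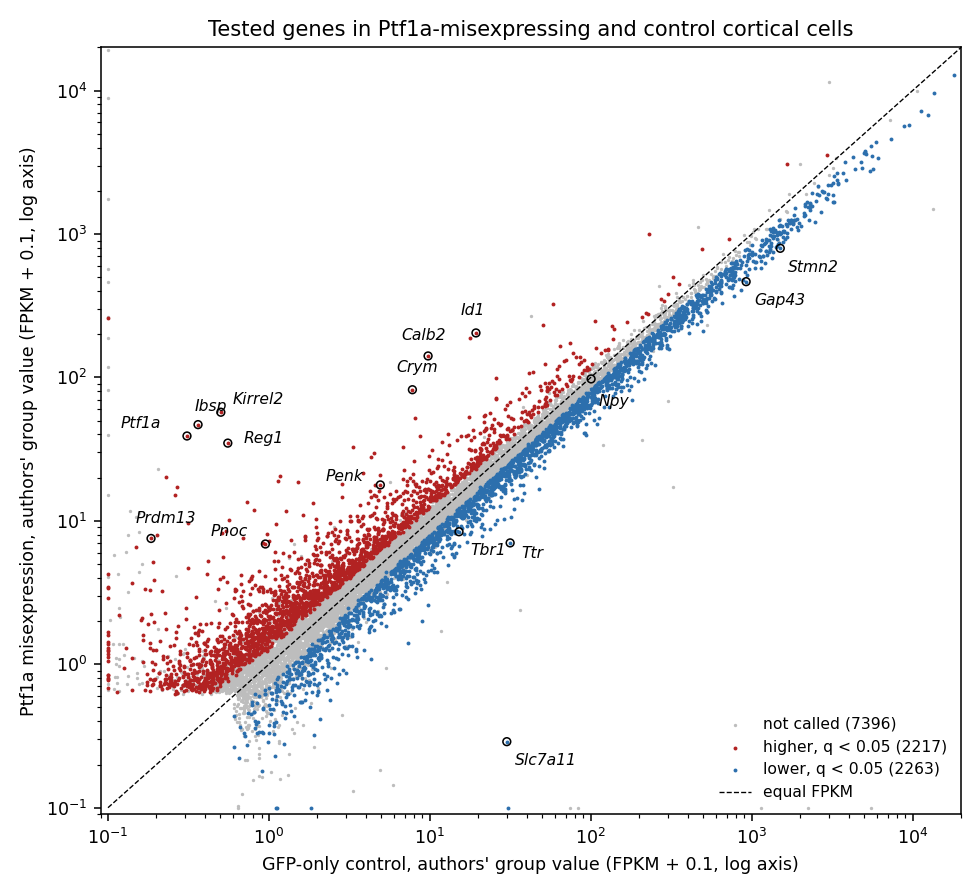
Authors' group value of each tested gene in the GFP-only control (x axis) and in Ptf1a misexpression (y axis), both in FPKM plus 0.1 on log axes, with genes past the authors' q threshold in colour and the dashed line marking equal values. Ptf1a, Ibsp, Kirrel2 and Prdm13 lie far above the line and Slc7a11 far below it, and most genes of high FPKM lie under the line.

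Partners and known direct targets of Ptf1a were examined as a group. Of 12 tested members with at least 1 FPKM, 6 rose and 1 fell, which missed the threshold (Fisher's exact test, adjusted p = 0.0532); adjusted over the list alone, 10 of the 14 tested members rose. Kirrel2, Prdm13 and the AP-2 factor Tfap2b (0.0630 to 2.00 FPKM) rose most, and Nphs1, which encodes nephrin, went from 0.0660 to 0.938 FPKM. Bhlhe22 went the other way, from 20.9 to 7.75 FPKM. The list passed under 5 alternatives, such as the 724 calls from a normal p of the deposited test statistic (adjusted p = 0.00433, exact test). It did not pass when stratified by expression (Mantel-Haenszel adjusted p = 0.130) or without genes shared among lists (adjusted p = 0.553, exact test). The latter setting removes Kirrel2, Prdm13 and Tfap2b, which other lists also hold, so it cannot speak to the list as fixed.

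The series title frames the study around an inhibitory peptidergic identity, so neuropeptide and transmitter genes were compared next. In the list fixed as inhibitory dorsal horn peptides, 4 of 5 tested members rose (adjusted p = 0.0276, Fisher's exact test, with 4 adjusted over the list alone). Sst, a risen member, also belongs to the cortical interneuron list and is not specific to inhibitory dorsal horn neurons. Penk, another risen member, is also in the basal progenitor list. Every member also belongs to the wider neuropeptide list. Penk, the enkephalin precursor (chromosome 4, 4060683 to 4065592, mm9), went from 4.82 to 17.7 FPKM. Gal, the galanin precursor (chromosome 19, 3409917 to 3414457, mm9), went from 3.59 to 12.8 FPKM. Pnoc, the nociceptin precursor (chromosome 14, 66019510 to 66044309, mm9), rose from 0.851 to 6.79 FPKM, and Sst from 41.3 to 78.6 FPKM. Npy, the most abundant of them, stood at 100.3 and 97.5 FPKM and was not called. Pdyn (dynorphin) stood at 0.547 and 0.264 FPKM in a row without a test. The wider neuropeptide list also holds secreted synaptic proteins of the Nxph and Cbln families. Of its 24 tested members with at least 1 FPKM, 9 rose and 6 fell (adjusted p = 0.0955 for the rises and 0.818 for the falls, exact tests, with 9 and 6 adjusted over the list alone). The rises passed with the normal p calls (adjusted p = 0.000143, exact test) but not without genes shared among lists (adjusted p = 0.903, exact test). That setting removes Penk, Gal, Pnoc, Sst and Tac2, so it cannot speak to the list as fixed. Nxph4 (0.416 to 5.50 FPKM) and Tac2 (0.684 to 4.02 FPKM), the latter also in the basal progenitor list, were also among the risen. The fallen, chosen after their values were seen, were Gcg (26.1 to 10.0 FPKM), Cck (13.1 to 6.81 FPKM), Cbln1, Cbln2, Adcyap1 and Rln1. Pomc, Nmb and Grp were not called, nor was Pyy (0.0337 and 7.89 FPKM), chosen after its values were seen.

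For GABA, the 2 synthetic enzymes both rose, Gad2 from 1.05 to 3.39 FPKM and Gad1 from 0.522 to 1.16 FPKM. The GABA transporter Slc6a11 (0.927 to 3.11 FPKM) and the chloride importer Slc12a2 (0.683 to 1.25 FPKM) rose too, making 4 of 6 members and 4 adjusted over the list alone (adjusted p = 0.0532, exact test). The list passed at a q under 0.01 (adjusted p = 0.0181, exact test) and with 2-fold calls (adjusted p = 0.0163, exact test). Stratified by expression, it did not pass, and its odds ratio went from 8.25 to 2.61. Gad1 and Slc12a2 were not called by the normal p. Slc6a17, Abat and Slc6a13 were not called, and Slc32a1, the vesicular GABA transporter (chosen after its value was seen), stood at 0.0658 and 0.104 FPKM in a row without a test. Glutamate genes as a group passed neither test, with 2 risen and 1 fallen of 10 (adjusted p = 0.857 in each direction, exact tests; 2 and 1 adjusted over the list alone). The vesicular glutamate transporter Slc17a6 stood at 7.05 and 6.38 FPKM and was not called, nor were Got1, Slc38a2 and Glud1, while Slc38a1 and Slc1a6 rose and Slc1a1 fell. Of monoamine and cholinergic genes 2 were tested, both below 1 FPKM, and Tph1 rose (0.138 to 0.708 FPKM; 1 adjusted over the list alone).

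**Figure D2:**
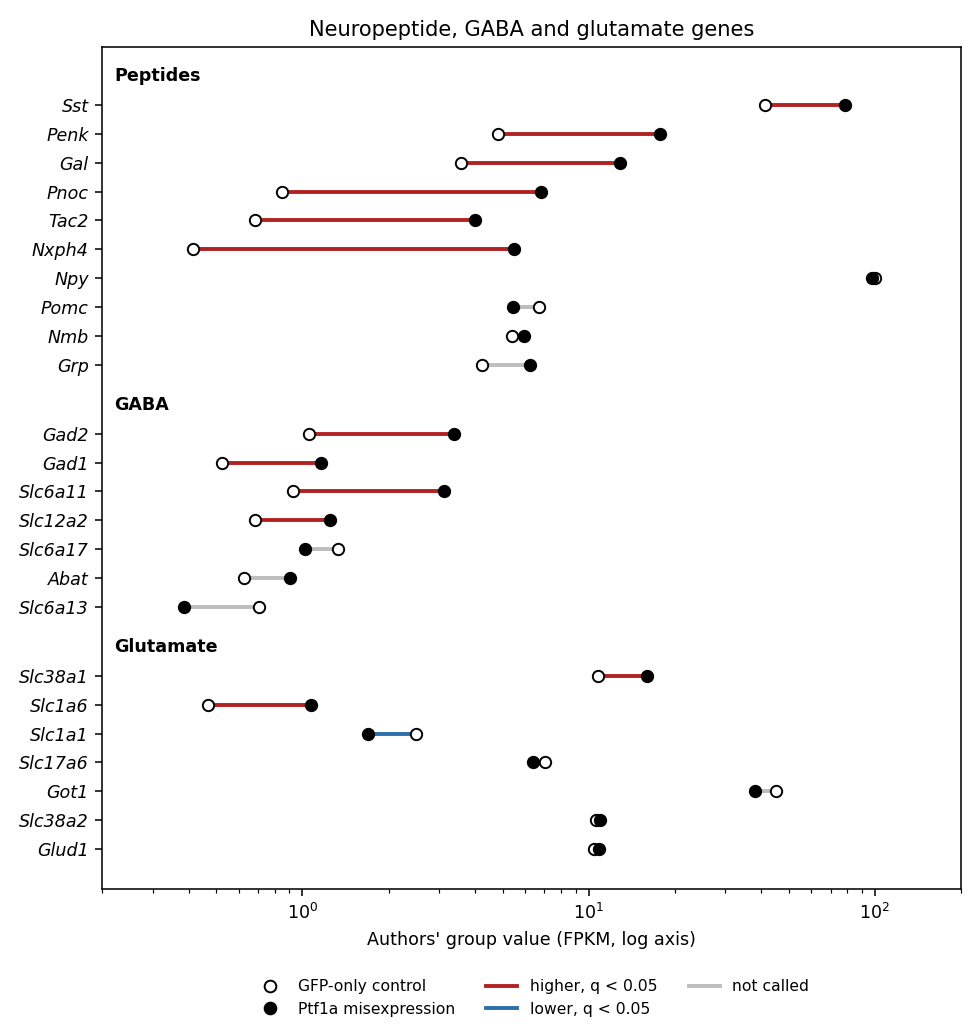
Authors' group values (FPKM, log axis) of named genes of the neuropeptide, GABA and glutamate lists. Open circles mark the GFP-only control and filled circles Ptf1a misexpression, joined by a line coloured by the authors' call. Pnoc spans 0.851 to 6.79 FPKM, while Npy and Slc17a6 show nearly equal values.

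Transcription factors of dorsal horn neurons gave uneven results. Among inhibitory dorsal horn factors 5 of 10 rose and 2 fell (adjusted p = 0.0773 for the rises, exact test, with 5 and 2 adjusted over the list alone). Ptf1a itself, Prdm13 and Tfap2b rose most. These counts include Ptf1a, which the construct carried, so its rise says nothing of the other factors. Rorb was not called. Lhx1, Lhx5 and Pax2, factors downstream of Ptf1a in the spinal cord, were chosen after their values were seen. Their rows had no test. Lhx1 stood at 0.0814 and 0.127 FPKM, Lhx5 at 0.236 and 0.582 FPKM and Pax2 at 0.0862 and 0.478 FPKM. Of the 17 excitatory dorsal horn factors 12 had no test. Among these Lmx1b, Prrxl1 and Phox2a, chosen after their values were seen, were listed at 0 in both groups. Of the tested factors with at least 1 FPKM, 3 of 4 rose (adjusted p = 0.0773, exact test, with 3 adjusted over the list alone). Ebf1 went from 1.41 to 18.7 FPKM, Isl1 from 2.58 to 4.53 FPKM and Lhx2 from 19.6 to 25.3 FPKM, while Lhx9 and Prrx1 were not called. Ebf1 and Isl1 also belong to the cortical interneuron list and Lhx2 to the pyramidal neuron list. Retinal amacrine and horizontal cell genes had 5 of 10 risen and 3 fallen (adjusted p = 0.0773 for the rises, exact test, with 6 and 3 of the 11 tested adjusted over the list alone). The calcium-binding protein Calb2 (calretinin) rose from 9.65 to 141 FPKM, Pax6 from 3.73 to 21.5 FPKM and Onecut2 from 0.108 to 0.772 FPKM. Cerebellar genes changed in few members, 3 risen and 1 fallen of 11 (adjusted p = 0.779 in each direction, exact tests; 5 and 1 adjusted over the list alone). Itpr1 and Car8 rose and Pcp4 fell from 59.9 to 35.7 FPKM.

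Transcripts of pancreatic acinar genes were higher in the Ptf1a samples. Of 14 tested members with at least 1 FPKM, 10 rose and 0 fell (adjusted p = 0.000293, Fisher's exact test; 10 adjusted over the list alone), and the list's median log2 difference was 4.78, above 100% of the random lists, or 2.34 with a pseudocount of 1. The digestive protease genes Prss2 (0.129 to 20.2 FPKM) and Ctrb1 (0.170 to 17.2 FPKM), the secreted protein gene Reg1 (0.455 to 34.7 FPKM) and the lipase gene Cel (0.0499 to 6.43 FPKM) led. At a q under 0.01 the list was no longer called, with an odds ratio of 3.91 in place of 10.7. Cela2a (0.0487 to 10.6 FPKM) and Try4 (0.0296 to 5.92 FPKM), chosen after their values were seen, did not pass the authors' test.

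Genes that mark pyramidal neurons, the class the electroporated progenitors normally produce, fell more often than others. Of 48 members 20 fell (adjusted p = 0.00907, Fisher's exact test) and 14 rose (adjusted p = 0.166, exact test), and 21 and 16 of the 50 tested did so adjusted over the list alone. The list's median log2 difference of -0.14 lay above 15.3% of the random lists of matched expression, so it was not extreme. The semaphorin receptor gene Plxnd1 fell from 1.89 to 0.515 FPKM and Bhlhe22 from 20.9 to 7.75 FPKM. Among fallen members chosen after their values were seen were the deep-layer factor Tbr1 (15.1 to 8.29 FPKM), Bcl11b (9.15 to 6.12 FPKM) and Fezf2 (20.0 to 15.6 FPKM). Crym (7.69 to 82.0 FPKM), Emx2 (0.511 to 3.13 FPKM) and Dkk3 (2.58 to 7.75 FPKM) rose, and Sox11, Lmo4 and Fam49a were not called. The call for the list was lost among genes of at least 5 FPKM (odds ratio 2.18 in place of 2.70) and with the normal p calls (adjusted p = 0.0631, exact test).

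Genes of the ganglionic eminence and cortical interneurons, the usual source of cortical GABA neurons, rose in 11 of 20 members and fell in 2 (adjusted p = 0.00205 for the rises, Fisher's exact test; 17 and 2 of the 24 tested adjusted over the list alone). Calb2 and Ebf1 moved most, followed by Zfp503 (0.0890 to 0.932 FPKM) and Rarb (0.133 to 0.916 FPKM). Dlx1as, Calb1, Cxcr7 and Dlx6as1 were not called. Cajal-Retzius and pioneer neuron genes had 4 of 8 risen and 2 fallen (adjusted p = 0.125 for the rises, exact test; 6 and 2 of the 11 tested adjusted over the list alone), with Nhlh1 going from 0.453 to 3.67 FPKM and Ebf3 from 0.0145 to 0.536 FPKM.

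Progenitor and cell cycle genes rose together. In the cell cycle list 48 of 51 members rose and 0 fell (adjusted p = 7.71e-31 for the rises, Fisher's exact test; 49 adjusted over the list alone), with a median log2 difference of 1.00. The cyclin gene Ccnd2 went from 25.7 to 99.2 FPKM, Cdk2 from 2.37 to 8.23 FPKM, Ccne1 from 0.393 to 1.47 FPKM and the proliferation marker Mki67 from 0.625 to 2.04 FPKM. In the radial glia list, genes of the neural stem cells of the cortex, 25 of 27 rose and 0 fell (adjusted p = 1.65e-15, exact test; 29 and 2 of the 32 tested adjusted over the list alone). Among them were Pax6, Sox3, Nes (1.03 to 5.15 FPKM) and Phgdh (50.0 to 232 FPKM). Of basal progenitor genes 12 of 23 rose and 4 fell (adjusted p = 0.00205 for the rises, exact test; 12 and 4 adjusted over the list alone), with the proneural factor Neurog1 going from 0.205 to 2.39 FPKM. Notch pathway and Id genes had 9 of 20 risen and 5 fallen (adjusted p = 0.0276 for the rises, exact test; 17 and 5 of the 27 tested adjusted over the list alone). Id1 rose from 19.2 to 204 FPKM, Id3 from 58.0 to 324 FPKM, Lfng from 0.518 to 3.25 FPKM and Nrarp from 0.668 to 2.98 FPKM. Cell cycle exit and p53 genes did not pass as a list, with 5 of 22 risen and 2 fallen (adjusted p = 0.798 for the rises, exact test; 8 and 2 of the 26 tested adjusted over the list alone). Trp53inp1, Sesn2, Btg2 and Cdkn1a (5.79 to 14.2 FPKM) rose. Astrocyte genes, which share members with the radial glia list, rose in 6 of 7 (adjusted p = 0.00205, exact test; 6 adjusted over the list alone). Aldh1l1, Sox9, Acsbg1 and Fgfr3 were among them, while Gja1 and Slc1a2 were not called.

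**Figure D3:**
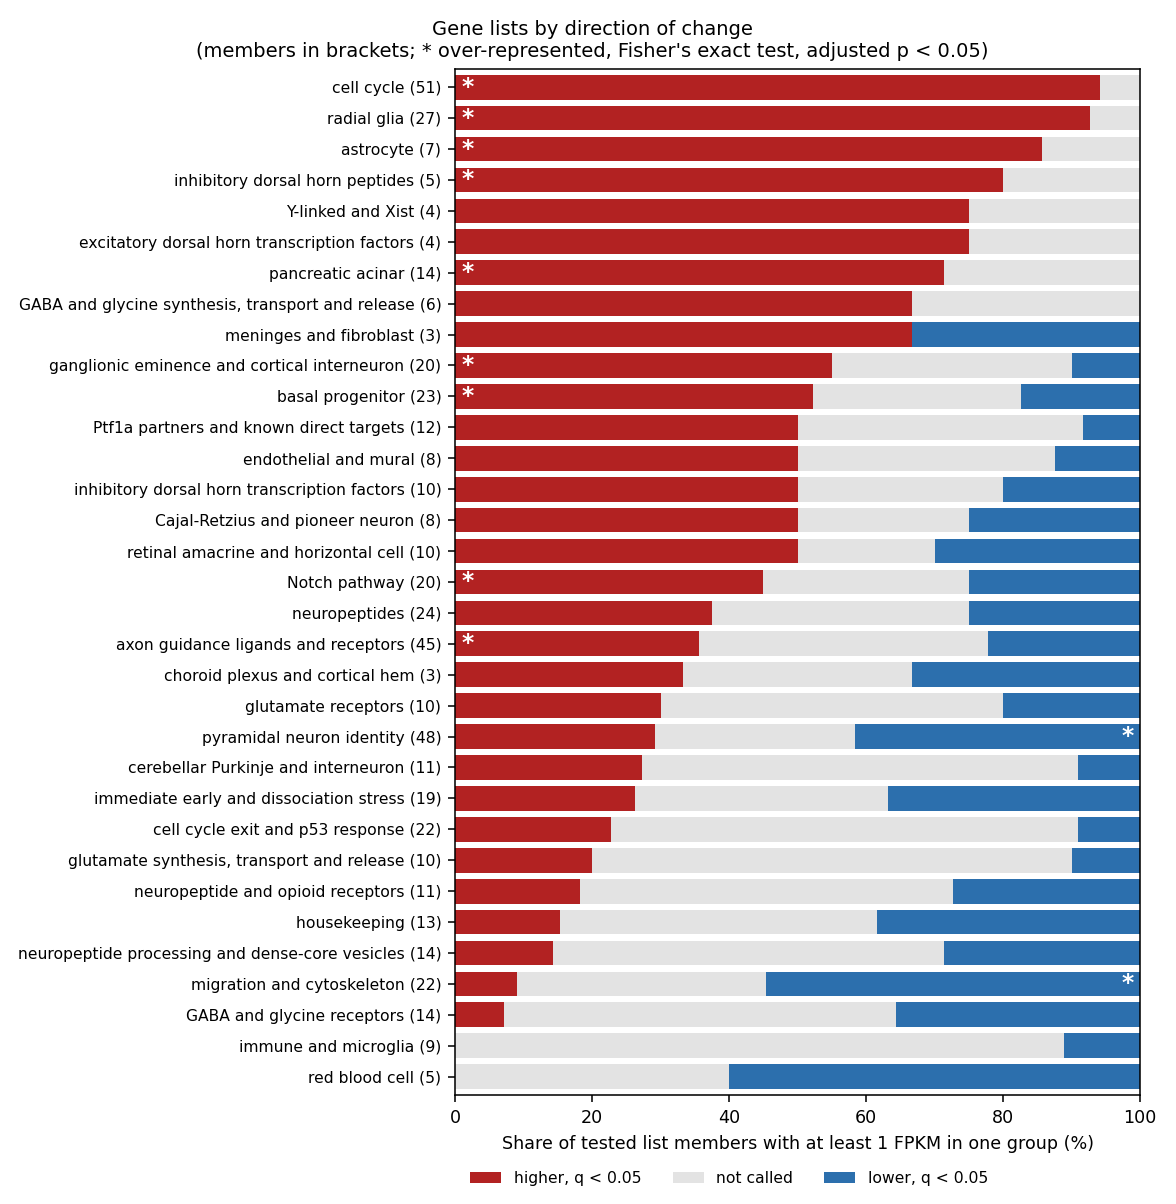
Share of each fixed gene list (tested members with at least 1 FPKM in either group, number in brackets, lists of 3 or more) that was higher (red), not called (grey) or lower (blue) in Ptf1a misexpression, with asterisks for lists over-represented by Fisher's exact test. In the cell cycle list 48 of 51 members were higher, and in the migration and cytoskeleton list 12 of 22 were lower.

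Genes of neuronal migration and the cytoskeleton fell in 12 of 22 members and rose in 2 (adjusted p = 0.00513 for the falls, Fisher's exact test; 12 and 4 of the 24 tested adjusted over the list alone). The growth cone gene Gap43 went from 923 to 465 FPKM, Stmn2 from 1504 to 794 FPKM and the neurofilament gene Nefl from 109 to 47.3 FPKM, while Reln rose from 0.244 to 0.678 FPKM. These are abundant transcripts, and abundance itself moved with the groups: the median log2 difference was 0.41 in the lowest of 10 bins of mean expression and -0.35 in the highest, where 653 of 1049 genes fell and 26 rose. Stratified by these bins, the list was no longer called (odds ratio 2.61 in place of 4.46). Axon guidance genes rose in 16 of 45 members and fell in 10 (adjusted p = 0.0276 for the rises, exact test; 16 and 10 adjusted over the list alone), with Efna5 (0.521 to 3.19 FPKM), Dcc (1.02 to 2.72 FPKM) and Plxnb1 risen. That call was lost under 6 alternatives.

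Receptor and peptide processing genes passed no list test. GABA and glycine receptors had 1 risen and 5 fallen of 14 (adjusted p = 0.461 for the falls, exact test; 1 and 5 adjusted over the list alone), among them Glra2 (7.26 to 2.76 FPKM), Gabra5 and Gabra2. Glutamate receptors had 3 risen and 2 fallen of 10 (adjusted p = 0.769 for the rises, exact test; 6 and 2 of the 16 tested adjusted over the list alone), with Grik1, Grid1 and Grik2 risen and Gria3 fallen. Neuropeptide and opioid receptors had 2 risen and 3 fallen of 11 (adjusted p = 1 for the rises and 0.857 for the falls, exact tests; 2 and 3 adjusted over the list alone). Ntsr2 rose from 0.312 to 4.13 FPKM and Crhr1 from 0.997 to 6.00 FPKM, while Mc4r (21.0 to 10.9 FPKM) and Oprl1 fell. Peptide processing and dense-core vesicle genes had 2 risen and 4 fallen of 14 (adjusted p = 0.779 for the falls, exact test; 2 and 5 of the 17 tested adjusted over the list alone), with Pcsk1, Syt4 (159 to 86.0 FPKM) and Pcsk1n fallen and Cadps risen.

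Markers of other cell types moved in different directions. Red blood cell genes fell in 3 of 5 (adjusted p = 0.187, exact test; 3 adjusted over the list alone). These were Hbb-y (32.0 to 10.6 FPKM), Hbb-b2 (90.2 to 40.7 FPKM) and Hba-x (8.83 to 1.92 FPKM), while Hba-a2 and Alas2 were not called. Microglial genes had 1 fallen of 9, Tyrobp (adjusted p = 0.857, exact test; 1 adjusted over the list alone), and C1qa, C1qb and Fcer1g were not called. Endothelial and mural genes had 4 risen and 1 fallen of 8 (adjusted p = 0.125 for the rises, exact test; 4 and 1 adjusted over the list alone). Pdgfrb (0.0286 to 1.20 FPKM), Ramp2, Esam and Rgs5 rose, with Egfl7, Cldn5, Vtn and Emcn not called. Meningeal genes had 2 risen and 1 fallen of 3 (adjusted p = 0.229 for the rises, exact test; 3 and 3 of the 6 tested adjusted over the list alone), namely Crabp2, Lgals1 and Dcn; Igf2, below 1 FPKM, also rose and Lum was not called. Oligodendrocyte genes had 0 called of 3 tested (Cnp, Mag and Mbp; 0 adjusted over the list alone). Choroid plexus and hem genes had 1 risen and 1 fallen of 3 (adjusted p = 0.779 in each direction, exact tests; 2 and 1 of the 4 tested adjusted over the list alone). Wnt5a went from 0.0710 to 3.22 FPKM, Ttr fell, Bmp7 rose from 0.157 FPKM and Rspo3 was not called.

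The Y-linked genes Ddx3y (1.04 to 2.71 FPKM), Eif2s3y (13.2 to 25.6 FPKM), Kdm5d and Uty rose, while Xist (4.17 and 3.42 FPKM) was not called. The sex of the pooled brains was not known here, so an effect of Ptf1a cannot be told from unequal shares of male brains. Of the list, 3 of 4 rose (adjusted p = 0.0773, exact test; 4 risen and 1 fallen of the 5 tested adjusted over the list alone). Immediate early and dissociation genes had 5 risen and 7 fallen of 19 (adjusted p = 0.752 and 0.252, exact tests; 6 and 7 of the 21 tested adjusted over the list alone). Arc and Egr1 (2.49 to 8.70 FPKM) rose and Npas4 fell. Of housekeeping genes 2 of 13 rose and 5 fell (adjusted p = 1 and 0.413, exact tests; 2 and 5 adjusted over the list alone). B2m and Polr2a rose, and Ppia (5150 to 3625 FPKM) and Eef1a1 (5043 to 3762 FPKM) fell. Over 9434 genes with at least 1 FPKM in both groups the median log2 difference was -0.06.

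Set among random lists of matched expression, list medians gave a partly different picture from the exact tests. The medians of the inhibitory dorsal horn peptide, radial glia, basal progenitor and cell cycle lists lay above 100% of random lists, those of the interneuron, Notch and astrocyte lists above 99.97%, 99.95% and 99.99%, and that of the axon guidance list above 91.7%. Among lists that missed the threshold, the neuropeptide (0.54) and Cajal-Retzius (1.25) medians lay above 100%, those of Ptf1a targets above 99.57%, retinal genes 99.81%, Y-linked genes 99.59%, meningeal genes 99.45%, endothelial genes 98.76% and excitatory dorsal horn factors 97.9%. The GABA synthesis and inhibitory dorsal horn factor medians lay above 91.34% and 91.31%, the latter list with Ptf1a itself among its members. At the low end, the red blood cell median (-1.26) lay above 0%, the microglial median above 0.85% and the migration median above 1.71% of random lists. The remaining medians lay between 7.12% and 95.37%.

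The count of called genes depended on the p used. The authors' p was not a normal tail of the deposited test statistic. Polr2a, for example, had a statistic of 1.90 and a p of 5e-05 in the authors' test, the smallest p, shared by 1803 genes. Put in place of the authors' p, a normal p of that statistic called 724 genes (392 higher and 332 lower), 713 of them among the 4480. It kept 77 of the 126 named called genes. Named genes lost that way include Tff2, Clps, Rnase1, Defb25, Cma1, Gad1, Slc12a2, Tac2, Isl1, Lhx2, Rarb, Sox3, Ccne1 and Reln, the first 5 because no statistic is given against a 0.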

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

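The tests of neuron share, pancreatic reads, uneven libraries, the Slc7a11 neighbourhood and the amino acid stress response were chosen only after the results they bear on were seen.

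Genes of the fixed lists that the authors' table left without a test, yet stood at 0.25 FPKM or more with Ptf1a and at least 4 times the control, drew attention because they lie outside the tested genes. Among transcription factors these were Pax2 (0.478 FPKM), Rbpjl (0.467 FPKM), Prox1 (0.372 FPKM) and Atoh1 (0.301 FPKM). Rbpjl encodes the acinar partner of Ptf1a in the pancreas, and its control value was 0.00509 FPKM. The others were Hspb1 (0.574 FPKM), Npvf (0.368 FPKM), Ntn4 (0.350 FPKM), Cdkn2b (0.342 FPKM), Notch3 (0.326 FPKM), Spink3 (0.306 FPKM), Folr1 (0.287 FPKM), Vipr2 (0.287 FPKM) and A930038C07Rik (0.283 FPKM). No error is known for any of them.

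Progenitor and cell cycle genes rose while neuronal cytoskeleton and ribosomal protein genes fell, in a table where change ran against abundance. After a cubic trend on expression level, transcript length and GC was removed, the cell cycle median was 0.917 (log2, 95% bootstrap interval 0.867 to 1.09, from 1.00) and the radial glia median 1.16 (0.778 to 1.43, from 1.18), which argues against the trend as the whole cause of either. The ribosomal protein genes, 79 of 81 with a known length, went from -0.58 to 0.0224 (-0.0761 to 0.0839). Their fall may come from that trend, but the fit included them, so a fall of their own cannot be told apart from it. The migration and cytoskeleton genes went from -0.34 to -0.276 (-0.367 to -0.0879). There the trend and a change of their own cannot be told apart because the interval reaches above the bound of -0.2. Radial glia genes exceeded the pooled median of 26 blood, vascular, meningeal, microglial and oligodendrocyte markers by 1.35 (0.656 to 1.82). By list, the meningeal median was 1.23, the vascular 0.85, the microglial -0.34 and the blood -1.26. Cells were sorted on GFP, so a lower share of neurons need not raise markers of these mostly unlabelled types. The comparison therefore cannot decide whether the share of neurons was lower. More progenitors among the sorted cells, or progenitor genes switched on in neurons, stay open as untested biological readings.

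Pancreatic acinar genes were higher in the Ptf1a samples, 10 of 14 of them called. Reads from pancreas cannot be excluded: 6 other enzymes, Pnlip and Amy2a5 among them, differed by a median of 0.0155 FPKM, against 5.02 FPKM for the called members, but they were picked from the uncalled ones. Uneven levels among the 3 Ptf1a libraries could give large rises with poor p values, as for Cela2a and Try4: 7 of 9 acinar genes higher by 4 log2 units or more had a p above the table's smallest, against 18 of 31 other such genes (Fisher's exact p = 0.440), which decides nothing, since those 31 include further pancreatic and gut products such as Reg3b, Ins2 and Ghrl. Activation by Ptf1a of part of its pancreatic programme remains a hypothesis.

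Slc7a11 fell from 30.0 to 0.189 FPKM. Loss or silencing of the whole surrounding region is argued against by the 9 tested genes within 2 Mb. Their median log2 difference was 0.0693 (range -0.763 to 1.69). These genes cannot speak to a loss or silencing confined to Slc7a11. For the amino acid stress response, 14 of its genes had a median of 0.128 (-0.246 to 1.14), with 5 risen and 3 fallen. The fallen were Asns (91.4 to 63.1 FPKM), Chac1 (12.1 to 8.03 FPKM) and Slc7a1. The risen were Cth, Psat1, Trib3, Phgdh, which is also in the radial glia list, and Sesn2, also in the p53 list. A fall shared by the whole set was not seen. Lower activity of part of the response cannot be decided from so mixed a set. No other explanation was tested, and an effect of Ptf1a on the gene remains a hypothesis.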

How the results depend on the processing

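The normal p calls, the tests stratified by expression, and those without Ptf1a, without genes of several lists, without shared loci or without genes at 0 were chosen after seeing the data. No paired analysis was possible because the table holds a single value per group, and for the same reason leaving out a replicate, limma, DESeq2 and edgeR were not run. Depth is unknown. Leaving out unnamed or multi-gene entries kept the counts within 1.5 times of 4480 called, 2217 risen and 2263 fallen, as did q under 0.01 (3071 called) and under 0.1 (5333). Requiring 5 FPKM in either group left 2718 called (849 risen), because fewer genes were tested, and 1 FPKM in both left 1358 risen. A fold of at least 1.5 left 2456 (915 fallen) and of at least 2 left 1014 (792 risen, 222 fallen), by construction. The normal p of the test statistic, put in place of the authors' p, called 724 (392 risen, 332 fallen). Why it differs from the authors' p was not tested. The share of called genes with a 2-fold change, 22.6%, became 25.2% with a pseudocount of 0.01, 9.11% with 1, 23.9% after centring and 25.5% with the authors' deposited folds. For lists, 13 of 70 tests passed, and 22 passed with 2-fold calls. Centring and leaving out Ptf1a could not change these calls. Odds ratios that no longer passed, with causes not tested, were as follows. At q under 0.01 these were acinar rises (3.91) and radial glia falls (0.108). With no FPKM minimum these were radial glia falls (0.202) and axon guidance rises (2.09), and at 5 FPKM axon guidance rises (2.17) and pyramidal falls (2.18). With 2-fold calls, radial glia falls (0.945), cell cycle falls (0.503) and migration falls (3.65) did not pass, and axon guidance rises turned to 0.902. Stratified by expression, axon guidance rises (2.01) and migration falls (2.61) did not pass. Without genes of several lists, radial glia falls (0.0955) and axon guidance rises (2.51) did not pass, and the inhibitory dorsal horn peptides could not be tested, as all members are in several lists. With the normal p, pyramidal falls (3.90), radial glia falls (0.554), cell cycle falls (0.295) and axon guidance rises (1.52) did not pass. Among named genes and other lists 1201 alternatives left direction and call as they were, including settings that could not change them, 37 brought an uncalled list test past the threshold, and the acinar, radial glia and cell cycle medians moved with a pseudocount of 1 without a change of sign (2.34, 0.92 and 0.83).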

Other observations

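The family tests below and the choice of the genes named were made after the results were seen. Grouping 109 families of at least 10 members by shared symbol stem, 7 families held more fallen genes than the rest and 3 more risen genes (218 Fisher's exact tests, adjusted). Ribosomal protein genes fell in 75 of 81 cases, with a median log2 difference of -0.58 (adjusted exact p = 1.54e-41). So did 12 of 14 Ndufa genes and 9 of 10 Ndufb genes, which encode complex I subunits and assembly factors (adjusted exact p = 3.32e-05 and 0.000293). Of genes with the Cox stem, 13 of 22 fell (adjusted exact p = 0.00360). Of the mitochondrial ribosome, 24 of 47 Mrpl genes fell (adjusted exact p = 0.000292), while the Mrps genes, with 12 of 29 fallen, did not pass (adjusted exact p = 0.122). The Atp stem, which also holds ion pump and vacuolar ATPase genes, had 23 of 54 fallen (adjusted exact p = 0.00736). The Trappc genes of vesicle tethering fell in 7 of 10 (adjusted exact p = 0.0241). On the other side, 12 of 21 kinesin (Kif) genes rose, among them the mitotic Kif11, Kif20a and Kif23 of the cell cycle list, as did 8 of 12 Sox genes and 7 of 12 Klf genes (adjusted exact p = 0.00230, 0.00638 and 0.0338). The Klf genes went both ways, with 4 of 12 fallen. Removing the trend with expression level, transcript length and GC brought the family medians closer to 0: Ndufa from -0.45 to -0.18, Ndufb from -0.49 to -0.18, Cox from -0.35 to -0.18, Mrpl from -0.30 to -0.13, Atp from -0.21 to -0.02 and Trappc from -0.43 to -0.24. The Kif, Sox and Klf medians went from 0.39, 1.23 and 0.36 to 0.34, 0.72 and 0.29. The 95% bootstrap intervals after removal included 0 for ribosomal protein, Cox, Atp and Klf genes.

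Beyond the lists, called genes that rose by 4 log2 units or more included the following. The insulin gene Ins2 was listed at 0 in controls and stood at 1.58 FPKM. Krt18 went from 0.215 to 9.51 FPKM, the zinc finger gene St18 from 0.467 to 10.0 FPKM, the urea cycle gene Ass1 from 1.07 to 20.5 FPKM and the stress-induced gene Nupr1 from 1.05 to 19.0 FPKM. Ghrl, the ghrelin precursor (0.0556 to 11.2 FPKM), Gkn3 (0.0372 to 11.7 FPKM) and Reg2 (0.0566 to 8.30 FPKM) showed differences as large without passing the authors' test. Of small RNA rows without a test, 49 stood at 1 FPKM or more, 32 of them listed at 0 in the control and 10 listed at 0 with Ptf1a. Among tested small RNAs, the microRNA rows Mir568 (listed at 0 in controls, 258 FPKM with Ptf1a) and Mir680-1 (30.4 FPKM in controls, listed at 0 with Ptf1a) were called, and a 0 in such rows can be a failed estimate.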
